A study of Rattus norvegicus with 12 samples.

How the data were processed

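Total RNA of the forebrain was taken from 12 male Long Evans rats, 6 kept in a standard cage (control) and 6 exposed for 3 hours to an environment new to them (exposed). Per the labels' protocols, RNA was extracted with Trizol and cleaned on RNeasy columns, biotin-labelled cRNA was made by the standard Affymetrix procedure, and each animal was measured on 1 array. The deposited table holds 1 intensity per probe set and array on a linear scale, from 12.56 to 34828, for 31042 probe sets of transcripts and 57 array control probe sets. How the authors corrected background, summarised probes and normalized the arrays is not given in the sources used here. The log2 medians of the 12 deposited arrays lay within 0.06 of each other and their upper quartiles within 0.07, under the limit of 0.1 set for normalizing again, so the deposited intensities were compared without further normalization. The number of arrays, 6 per group, limits the precision of each value, and the depth behind an intensity is not defined as it is for counts.

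Intensities were raised to a floor at the 20th percentile of all values over the 12 arrays (an intensity of 53.8, or 5.75 on the log2 scale) and transformed to log2. On all 12 arrays 5216 probe sets were at this floor, and 0 of the probe sets that passed had a whole group at it. A linear model with the group as its only term was fitted to each probe set with lmFit of limma 3.58.1 in R 4.3.3, followed by eBayes with a mean-variance trend. The prior degrees of freedom of that fit were 0.79, and 3.2 without the probe sets at the floor on all arrays. The p-values were adjusted by Benjamini-Hochberg over 31042 probe sets, with the array control probe sets left out and no filter on dim ones, and an adjusted p under 0.05 counted as passed. Changes are exposed minus control.

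Probe sets were named from the platform annotation, with symbols looked up through the Entrez gene ID in the RefSeq gene table of the rat, which changed 0 symbols and left 68 IDs unmatched. One gene symbol was given for 20832 probe sets, several for 436 and none for 9831. Of the 796 probe sets that passed, 213 had no single symbol and are not named. Results per gene use the probe set with the highest mean over the 12 arrays. Probe set identifiers are given in the result tables and not in the text. Genome positions are not given, since the probe sequences were not among the sources used here.

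There were 27 gene lists, of which 15 are markers of cell types and regions, and 592 of their 708 symbols were matched to a probe set. For each list the members that passed in limma were counted, both over all probe sets and adjusted over the list alone. The shift of the list against all other genes was tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg over the 27 lists, and again with an estimated correlation. With an estimated correlation the calls of the immediate early, activity-regulated effector and heat shock lists held, and those of the glucocorticoid, endothelial and meningeal lists did not. The mean over a list per animal was compared by an exact two-sided permutation test over every assignment of 6 of the 12 animals, as were 9 single genes. For genes with several probe sets, the log2 difference between each probe set and the brightest one of its gene was fitted in limma, with Benjamini-Hochberg over 6609 pairs.

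The genes named in the text were set by a rule. It takes the 10 genes with the largest increase and the 10 with the largest decrease among those whose brightest probe set passed and has 1 symbol, the 10 genes of the single gene check whatever their result, and up to 4 members with the smallest p of each list described. Genes named outside the rule are said to be chosen after their values were seen. The groups, the fit, the lists, this rule and the first set of alternatives were fixed before the data were examined.

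The first set of alternatives was quantile normalization, centring each array on its median, leaving out the 40% of probe sets with the lowest mean, a floor at the 10th or 40th percentile, eBayes without a trend or in its robust form, array weights, the replicate number as a block, covariates for striatum markers, oligodendrocyte markers and RNA quality, leaving out probe sets whose names end in _s_at, _x_at or _a_at, and leaving out each animal in turn. Lists were also tested with the mean of all probe sets of a gene. RNA quality was taken as the log2 difference between 3 prime and 5 prime control probe sets of Gapdh and beta-actin. Added after seeing the data were leaving out 3 arrays, leaving out the probe sets at the floor on all arrays, and the replicate numbers 1 to 3 and 4 to 6 as a term with 2 levels. The 3 arrays were control 4, with high olfactory bulb and neuroblast markers, and exposed animals 3 and 5. The latter had the lowest median correlation with their own group (0.995 for both), while control 4, at 0.997, did not stand apart by this measure. Random splits of the animals into groups of 6 were drawn 100 times from 462 possible ones.

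The steps were tested on simulated data of the same size and spread. Changed probe sets and pairs were placed among the brighter probe sets only. Values were drawn independently of each other and without a floor. Of 50 probe sets changed by each amount, 60% were recovered at a log2 change of 0.25, 86% at 0.5, 96% at 1 and 100% at 2, with 11 false calls among 31042 probe sets. Of pairs made to move apart by 1 on the log2 scale 20 of 20 were recovered, with 3 false calls among the others. These 3 are a larger share of the pairs called than the threshold of 0.05 aims at. The recovery rates do not cover dim probe sets, values at the floor or lists of correlated genes, since these were not simulated. All value columns of the table were used.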

Results

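Forebrain RNA of 12 male Long Evans rats, each 6 weeks old and housed alone, was measured on Affymetrix rat expression arrays, 1 animal per array. The control group was 6 animals kept in a standard cage, and the exposed group was 6 animals placed for 3 hours in an environment new to them, with objects that varied in shape and colour. Values are probe set intensities as deposited, in arbitrary linear units, and changes are given on the log2 scale as exposed minus control, with the standard error of the limma fit (6 animals per group). The median intensity of an array lay between 235 and 245 over the 12 arrays. The number of arrays limits the precision of each value. The labels state the purpose of the series as finding genes that rise after the exposure, and the design gives 1 comparison, that of the exposed group with the control group.

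The forebrain of exposed animals held more RNA of genes that neurons switch on when they are active. Transcription factors of the Egr, Fos and Nr4a families and Arc, a protein of synapses, were among the largest increases, from 2.41-fold for Egr1 to 12.4-fold for Egr2. Genes of heat shock proteins and chaperones rose as a group by less, with a median log2 change of 0.14 over 23 genes, and genes that glucocorticoid hormones induce rose by a median of 0.23 over 30 genes, a call that was lost at adjusted p = 0.11 with an estimated correlation. The decreases were small, with no probe set lowered 2-fold or more. Markers of neurons, astrocytes, oligodendrocytes and microglia gave no shift of their list that passed the test.

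At a Benjamini-Hochberg adjusted p under 0.05 in limma, 610 of 31042 probe sets were higher in exposed animals and 186 were lower. An unadjusted p under 0.05 was reached by 4094 probe sets. With 1 probe set per gene, 492 of 14217 genes passed, 372 of them higher and 120 lower. An increase of 2-fold or more was seen for 25 of the probe sets that passed and a decrease of that size for 0, and with 1 probe set per gene 15 genes rose by that much. The median log2 change was 0.29 among the higher probe sets and -0.21 among the lower ones. Between the animals numbered 1 to 3 and 4 to 6 in the labels 3 probe sets passed in limma, and some gene lists differed. Chance order of the numbers was not excluded, and the labels do not say what the numbers stand for. Within animals numbered 1 to 3 (3 per group) 66 probe sets were higher and 9 lower, and within those numbered 4 to 6 the counts were 31 and 2. All 796 probe sets that passed with 12 animals had the same direction in both number sets, which hold the animals they were selected on.

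Egr2, a zinc finger transcription factor, had the largest increase, 3.63 ± 0.14 on the log2 scale (12.4-fold, adjusted p = 2.06e-07). Fos, a subunit of the AP-1 transcription factor, rose by 2.77 ± 0.16 (6.84-fold, adjusted p = 8.65e-06), and its relative Fosb by 2.46 ± 0.17 (5.51-fold, adjusted p = 2.82e-05). Arc rose by 2.57 ± 0.16 (5.96-fold, adjusted p = 1.91e-05). The orphan nuclear receptors Nr4a1 and Nr4a3 rose 3.34-fold (adjusted p = 4.18e-05) and 2.50-fold (adjusted p = 2.87e-07). Inhba, which codes for an activin subunit, rose 3.18-fold (adjusted p = 0.000201). Egr4 (2.43-fold, adjusted p = 6.77e-06), Egr1 (2.41-fold, adjusted p = 4.67e-08) and the inducible cyclooxygenase gene Ptgs2 (2.39-fold, adjusted p = 6.90e-06) complete the 10 largest increases. For each of these 10 genes, 6 of 6 exposed animals lay above every control animal. Within the animals numbered 1 to 3 alone, the log2 changes of these 10 genes ran from 1.11 to 3.42, and within those numbered 4 to 6 from 1.31 to 3.85. These changes are those of the brightest probe set of each gene. Dimmer probe sets of Fos (log2 change -0.02), Egr2 (1.95), Inhba (0.40), Egr4 (0.19) and Nr4a3 (0.31) moved apart from it in limma. The largest adjusted p of the difference was 0.00675. Their mean log2 intensity was 6.18 to 7.34, and only that of Egr2 passed by itself (adjusted p = 2.55e-05).

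**Figure D1:**
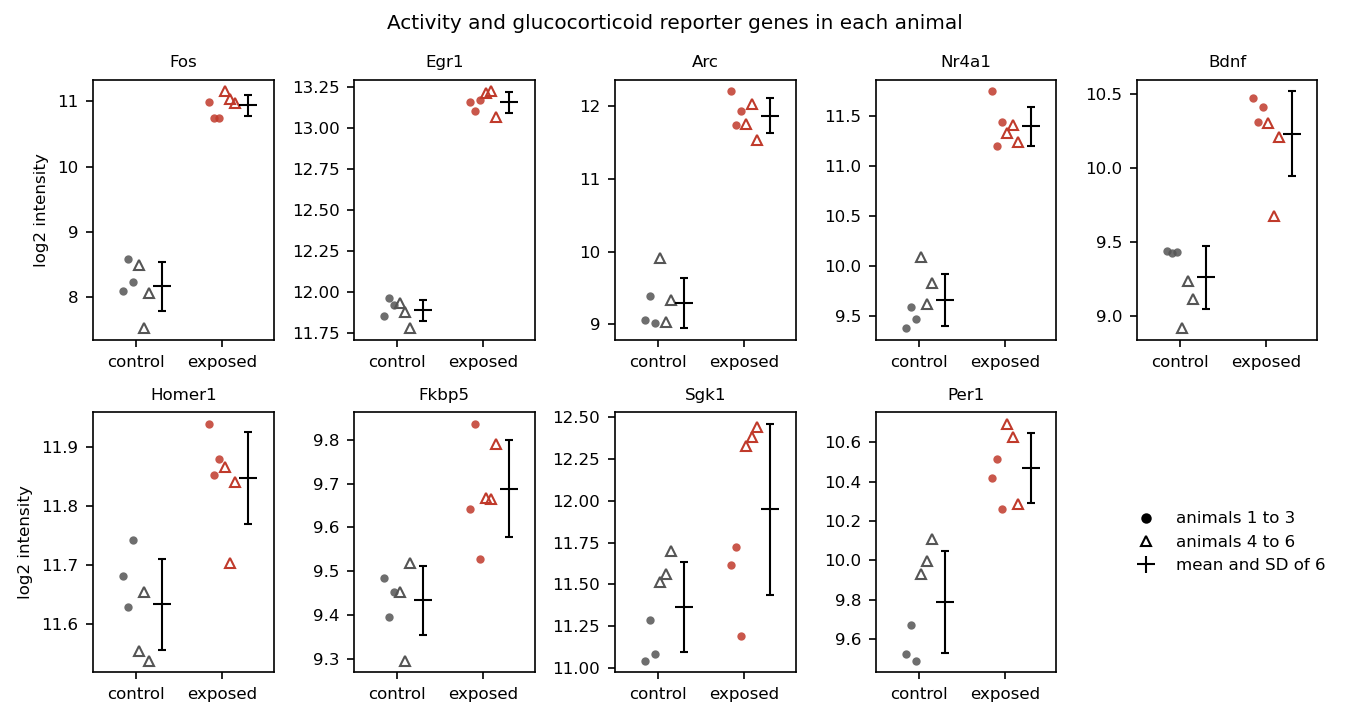
Log2 intensity (vertical axis) of the 9 genes of the single gene check in control animals and exposed animals, 1 symbol per animal, with filled circles for animals numbered 1 to 3, open triangles for those numbered 4 to 6, and a black bar for the mean ± SD of 6. The Fos symbols of the exposed group all lie above the control group, whose mean is 8.17, and those of Sgk1 overlap the control group.

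A set of 10 genes that report neuronal activity or glucocorticoid exposure had been named for a test that assumes no distribution, and 9 of them were measured, since the annotation names no probe set for Npas4. Mean intensity of Fos went from 296 ± 72.3 (SD, n = 6) in control animals to 1979 ± 220 (SD, n = 6) in exposed animals, and that of Egr1 from 3794 ± 170 to 9150 ± 390. Arc went from 642 ± 169 to 3773 ± 623, and Nr4a1 from 821 ± 155 to 2724 ± 392. Bdnf, a neurotrophin gene, went from 620 ± 87.7 to 1223 ± 214 (1.96-fold, adjusted p = 0.00391 in limma), and Per1, a clock gene that glucocorticoids also induce, from 896 ± 161 to 1425 ± 175 (log2 change 0.68, adjusted p = 0.0149). Fkbp5, a cochaperone of the glucocorticoid receptor, went from 693 ± 36.9 to 827 ± 63.5 (1.19-fold, adjusted p = 0.0320). In each of these 7 genes 6 of 6 exposed animals lay above every control animal, and the exact two-sided permutation test over every assignment of 6 of the 12 animals gave p = 0.00216, the smallest it can give (0.00278 after Benjamini-Hochberg over the 9 genes). Homer1, a scaffold gene of the postsynaptic density, went from 3180 ± 170 to 3688 ± 194 at its brightest probe set (1.16-fold, adjusted p = 0.0262, exact permutation p = 0.00433, 5 of 6 animals above every control). Sgk1, a kinase gene induced by glucocorticoids, went from 2676 ± 493 to 4153 ± 1366 and did not pass in limma (log2 change 0.58, adjusted p = 0.275), with 4 of 6 animals above every control and an exact permutation p of 0.0368, also 0.0368 after adjustment. Its log2 change was 0.37 within the animals numbered 1 to 3 and 0.79 within those numbered 4 to 6. With these number sets as a term in the fit, an alternative chosen after seeing the data, its adjusted p was 0.0185. With RNA quality as a covariate it was 0.0381, and over all 28 alternatives it ran from 0.0185 to 0.452. With the RNA quality covariate the calls of Fkbp5 (adjusted p = 0.0549) and of the brightest Homer1 probe set (adjusted p = 0.107) were lost. They were kept in 16 and 18 of the 28 alternatives. When each animal was left out in turn, the adjusted p of Fkbp5 was above 0.05 in 10 of 12 fits (0.0501 to 0.0710) and that of the brightest Homer1 probe set in 8 of 12 (0.0528 to 0.0592). Per1 missed the threshold at 0.0741 when control 4 and exposed animals 3 and 5 were left out together.

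Among immediate early transcription factors, the first genes transcribed when a neuron is stimulated, 17 of 23 measured genes rose and 0 fell in limma. Adjusted over the list alone, 19 rose and 0 fell. Ier5 rose 1.94-fold (adjusted p = 1.93e-07) and Egr1, Egr2 and Nr4a3, given with the largest increases, also belong to this list. The median log2 change of the list was 0.87, and the mean over its genes was 1.00 ± 0.07 (SD, n = 6) above the control mean, whose own SD was 0.06, with 6 of 6 animals above every control (exact two-sided permutation p = 0.00216). The shift of the list passed the camera test (adjusted p = 1.69e-37, and adjusted p = 0.000266 with an estimated correlation).

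Among activity-regulated effector genes, which code for synaptic, secreted and signalling proteins made after neurons fire, 23 of 39 rose and 0 fell. Adjusted over the list alone, 27 rose and 0 fell. Gadd45b, a gene of DNA demethylation and stress signalling, rose 2.26-fold (adjusted p = 2.72e-05, 6 of 6 animals above every control), and Dusp5, a phosphatase that acts on ERK, rose 2.30-fold (adjusted p = 2.76e-05, 6 of 6). Arc and Ptgs2 are the other members with the smallest p. The median log2 change was 0.33 and the mean over the list was 0.48 ± 0.05 (SD, n = 6) above the control mean (exact two-sided permutation p = 0.00216, camera adjusted p = 4.15e-33, and adjusted p = 0.000266 with an estimated correlation).

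Among glucocorticoid-induced genes, 6 of 30 rose and 0 fell, and 28 of the 30 log2 changes were positive. Adjusted over the list alone, 18 rose and 1 fell. The members with the smallest p were Dusp1, a phosphatase of MAP kinases (2.08-fold, adjusted p = 0.000301), Cdkn1a, an inhibitor of the cell cycle (1.42-fold, adjusted p = 0.00251), the repressor Bcl6 (1.28-fold, adjusted p = 0.0105) and Per1, each with 6 of 6 animals above every control. Dusp1 and Cdkn1a also belong to the activity lists. The mean over the list was 0.30 ± 0.13 (SD, n = 6) above the control mean, whose SD was 0.11, with 5 of 6 animals above every control (exact two-sided permutation p = 0.00649). The list passed camera (adjusted p = 2.44e-12), and this call was lost at adjusted p = 0.11 with an estimated correlation. In both groups the mean over the list was also higher in animals numbered 4 to 6 than in those numbered 1 to 3, by 0.19 in control animals and 0.22 in exposed animals. Within animals numbered 1 to 3 its median change was 0.21 (camera adjusted p = 2.78e-11) and within animals numbered 4 to 6 it was 0.26 (camera adjusted p = 2.91e-16). With the 2 number sets as a term in the fit, 18 of 30 members rose, while within either set alone 0 members passed in limma.

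Among heat shock and chaperone genes, 12 of 23 rose and 0 fell. Adjusted over the list alone, 18 rose and 0 fell. Hspb1, a small heat shock protein, rose 1.83-fold (adjusted p = 0.000964), the Hsp40 family member Dnajb5 1.52-fold (adjusted p = 0.000104), the cochaperone gene Bag3 1.41-fold (adjusted p = 0.000745) and Hspa5, the chaperone of the endoplasmic reticulum, 1.39-fold (adjusted p = 0.00101), with 6 of 6 animals above every control in each. The mean over the list was 0.25 ± 0.05 (SD, n = 6) above the control mean (exact two-sided permutation p = 0.00216, camera adjusted p = 6.91e-20, and adjusted p = 0.00669 with an estimated correlation). Within animals numbered 1 to 3 and within those numbered 4 to 6, the median change was 0.17 and 0.16 for this list, 0.75 and 0.95 for the immediate early list, and 0.27 and 0.31 for the effector list. Each passed camera in both sets (largest adjusted p = 1.5e-14). The members that passed in limma within the 2 sets were 2 and 0 for the heat shock list. They were 9 and 8 for the immediate early list, and 8 and 2 for the effector list.

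**Figure D2:**
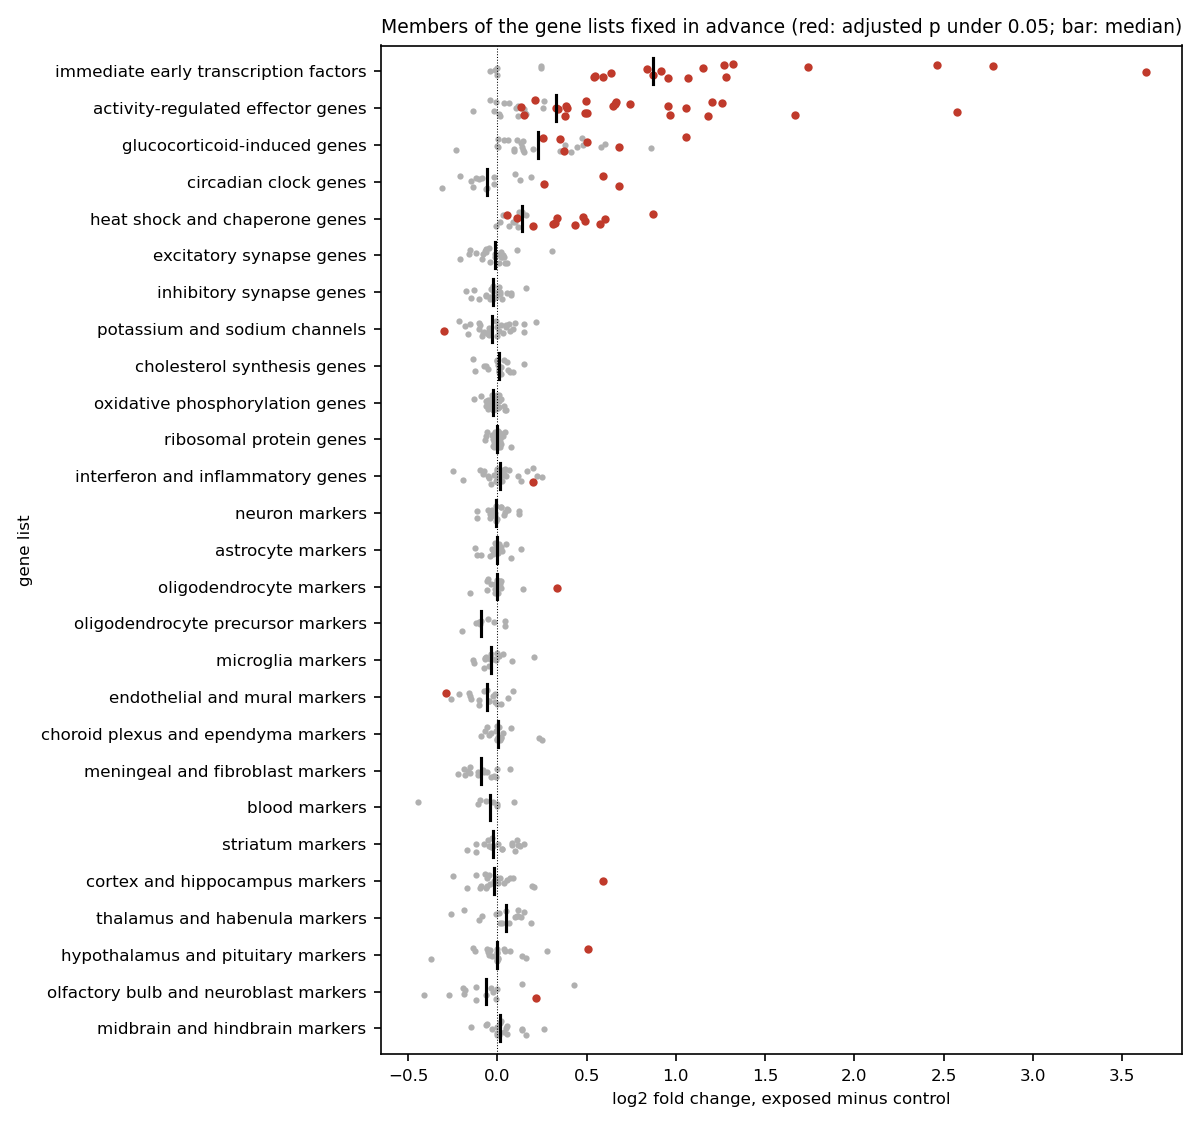
Log2 fold change, exposed minus control (horizontal axis), of each member of the 27 gene lists (vertical axis), 1 dot per gene, red where the adjusted p was under 0.05 and grey elsewhere, with a black bar at the median of the list. The bar lies at 0.87 for the immediate early list and at 0.33 for the activity-regulated effector list.

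Of the genes of the circadian clock, 3 of 17 rose and 0 fell, the same counts as when adjusted over the list alone. Per1, Per2 (1.51-fold, adjusted p = 0.0278) and Cry2 (1.20-fold, adjusted p = 0.00466), which code for repressors of the clock, rose in 6 of 6 animals. Dbp, a target of the clock, had a log2 change of -0.31 (adjusted p = 0.239, and 0.0104 with the number sets as a term in the fit). The list as a whole did not pass camera (adjusted p = 0.929), with a median of -0.06 and a mean of 0.04. Per2 differed between the number sets as well, by 0.38 on the log2 scale (adjusted p = 0.0318). Its call between the groups was lost in 7 of 12 fits with 1 animal left out (adjusted p 0.0519 to 0.0639), while with the number sets in the fit its adjusted p was 3.96e-05. At a dimmer Per2 probe set (mean log2 intensity 8.61) the log2 change between the groups was 0.01. It moved apart from the brightest Per2 probe set (adjusted p of the difference 0.0418 in limma).

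The 10 largest decreases ran from 1.26-fold to 1.41-fold. Ptprdl was 1.41-fold lower (adjusted p = 0.00187), the doublecortin-like kinase gene Dclk3 1.40-fold (adjusted p = 0.000349), Mex3b, an RNA-binding protein, 1.40-fold (adjusted p = 0.000528). The zinc finger gene Zc3h6 was 1.40-fold lower (adjusted p = 0.00322). Lrrc17 was 1.39-fold lower (adjusted p = 0.00958), the transcription factor gene Klf11 1.35-fold (adjusted p = 0.00220) and Ccdc177 1.26-fold (adjusted p = 0.00476). In each of these 7 genes 6 of 6 exposed animals lay below every control animal. Dact2 (1.33-fold lower, adjusted p = 0.0215), Ddit4l (1.33-fold, adjusted p = 0.0399) and Rasgef1c (1.30-fold, adjusted p = 0.0449) were below every control in 6, 5 and 4 of 6 animals. With 1 animal left out in turn, the adjusted p was above 0.05 in 9 of 12 fits for Ddit4l (0.0550 to 0.0946) and Rasgef1c (0.0590 to 0.104), and for Dact2 in 3 of 12 (0.0521 to 0.0524), those without control 6 or exposed animals 1 or 2. The 3 prime minus 5 prime difference of the array control probe sets, a sign of RNA quality, was 0.39 ± 0.05 (SD, n = 6) in control animals and 0.45 ± 0.07 in exposed animals (exact two-sided permutation p = 0.0823). With this RNA quality covariate 498 probe sets were higher and 72 lower, and the calls of Dact2 (adjusted p = 0.0861) and Rasgef1c (adjusted p = 0.169) were lost. Over the 28 alternatives the call was kept in 22 for Dact2, 15 for Ddit4l and 15 for Rasgef1c. Lrrc17 lost its call with the floor at the 40th percentile. Klf11 (adjusted p = 0.0526) and Ccdc177 (adjusted p = 0.0792) lost theirs with the replicate number as a block. With that block 5 of the 10 decreases kept their call. Ptprdl, Dclk3, Mex3b and Zc3h6 kept it in all 28 alternatives. The count of lower probe sets was 103 without control 3, 112 without control 5, 117 without control 6 and 104 without exposed animal 1.

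Of the 15 lists of cell type and region markers, 10 had no member that passed. Endothelial and mural markers were lower as a list, with a median of -0.06 over 19 genes (camera adjusted p = 0.0202, exact two-sided permutation p = 0.0238 for the mean over the list). This call was lost at adjusted p = 0.592 with an estimated correlation. In this list 1 of 19 fell, Slco1a4, a transporter of the blood-brain barrier (1.22-fold lower, adjusted p = 0.00364, 6 of 6 animals below every control), and 0 rose. Adjusted over the list alone, 2 fell. Meningeal and fibroblast markers were lower as a list, with a median of -0.09 over 16 genes (camera adjusted p = 0.0159, exact two-sided permutation p = 0.0649). This call was lost at adjusted p = 0.663 with an estimated correlation. In limma 0 of 16 passed, and 0 when adjusted over the list alone, their smallest unadjusted p being 0.0229 for Col1a2. Both calls were also lost without control 3 (adjusted p = 0.0539 for both) and without exposed animal 4 (0.0801 and 0.0994). That of the endothelial list was lost without control 2 (0.0515) and exposed animal 6 (0.0766). Within animals numbered 1 to 3 neither list passed (0.18 and 0.124), and within those numbered 4 to 6 both did (0.0393 and 0.0366).

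None of the other 13 marker lists passed camera. The adjusted p was 0.929 for neuron (20 genes), 0.933 for astrocyte (19), 0.929 for oligodendrocyte (17), 0.270 for oligodendrocyte precursor (9), 0.773 for microglia (17), 0.929 for choroid plexus and ependyma (18) and 0.923 for blood markers (8). For regions it was 0.933 for striatum (21), 0.933 for cortex and hippocampus (23), 0.257 for thalamus and habenula (17), 0.933 for hypothalamus and pituitary (23), 0.923 for olfactory bulb and neuroblasts (15) and 0.929 for midbrain and hindbrain (18). Single members that rose were Nr4a2 among cortex and hippocampus markers (log2 change 0.59, adjusted p = 0.00113), the stress hormone gene Crh among hypothalamus markers (1.42-fold, adjusted p = 0.0277), Cd24 among olfactory and neuroblast markers (1.16-fold, adjusted p = 0.0171) and the small heat shock gene Cryab among oligodendrocyte markers (1.26-fold, adjusted p = 0.0320), each in 6 of 6 animals above every control. The call of Crh was lost in 6 and that of Cryab in 9 of 12 fits with 1 animal left out (adjusted p 0.0586 to 0.0651 and 0.0524 to 0.0737), and both were also lost with the RNA quality covariate. Adjusted over the list alone, 2 oligodendrocyte and 2 olfactory markers rose, 1 cortex and 1 hypothalamus marker rose, and 1 striatum, 1 hypothalamus and 1 olfactory marker fell. The olfactory list was 0.56 above the control mean in control 4, while the other controls lay between -0.14 and -0.08.

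None of the other pathway lists passed camera, with adjusted p = 0.929 for excitatory synapse (24 genes), 0.773 for inhibitory synapse (24), 0.708 for potassium and sodium channel (30), 0.929 for cholesterol synthesis (20), 0.181 for oxidative phosphorylation (38), 0.923 for ribosomal protein (33) and 0.773 for interferon and inflammatory genes (31). The oxidative phosphorylation list passed at 0.00431 without control 1, 0.0434 without control 2 and 0.0275 without exposed animal 6, in each case lower in exposed animals, while with an estimated correlation and all animals its adjusted p was 0.955. It passed within animals numbered 4 to 6 (adjusted p = 0.00648) and not within those numbered 1 to 3 (adjusted p = 0.94). Kcna4, a potassium channel gene, fell (1.23-fold lower, adjusted p = 0.00791, 6 of 6 animals below every control), and Nfkb1, a subunit of NF-kappa-B, rose (1.15-fold, adjusted p = 0.00761, 6 of 6). In 7 lists the median, the mean and the camera direction differed in sign, and 0 of these passed: circadian clock, ribosomal protein, neuron, oligodendrocyte, striatum, cortex and hippocampus, and hypothalamus and pituitary.

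Probe sets of the same gene were compared next, since they can read different parts of its transcripts. Homer1 is measured by 5 probe sets, told apart here by their mean log2 intensity in control animals, and 2 of them rose strongly. The probe set with a control mean of 8.25 rose by 2.32 ± 0.17 (4.99-fold, adjusted p = 4.49e-05) and the one with a control mean of 10.04 by 2.03 ± 0.33 (4.08-fold, adjusted p = 0.00761), each with 6 of 6 animals above every control. The log2 change was 0.21 at the brightest (control mean 11.63), 0.18 at the one with a control mean of 9.23 (adjusted p = 0.487) and 0.16 at the one with a control mean of 10.85 (adjusted p = 0.371), with 5 of 6 animals above every control in each. The difference between either strong probe set and each of the other 3 ran from 1.82 to 2.16 (largest limma adjusted p = 0.0216, exact two-sided permutation p = 0.00216 for each). Within animals numbered 1 to 3 the 2 strong probe sets changed by 1.94 and 1.44, and within those numbered 4 to 6 by 2.70 and 2.62. For the one with a control mean of 10.04 the difference between the number sets in this change did not pass in limma (unadjusted p = 3.14e-06, adjusted p = 0.0976). Its mean in control animals was 10.78 in numbers 1 to 3 and 9.30 in numbers 4 to 6. In exposed animals it was 12.21 and 11.93. At the other strong probe set these means were 8.62 and 7.87 in control animals, and 10.56 and 10.57 in exposed animals.

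**Figure D3:**
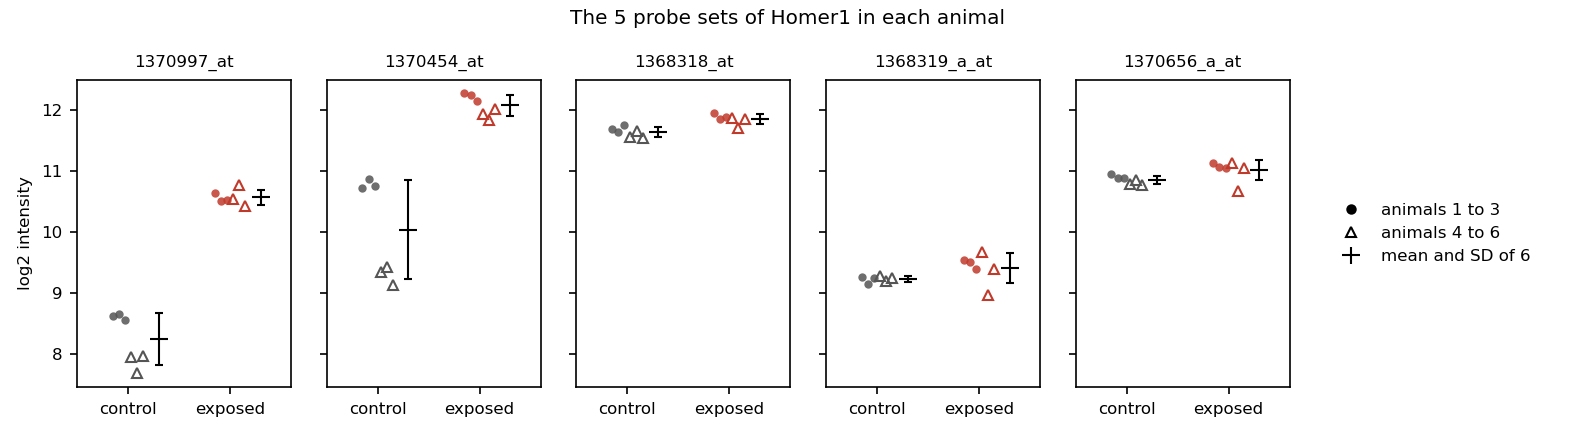
Log2 intensity (vertical axis) of the 5 Homer1 probe sets in control animals and exposed animals, 1 symbol per animal, with filled circles for animals numbered 1 to 3, open triangles for those numbered 4 to 6, and a black bar for the mean ± SD of 6. The panel with the largest change has means of 8.25 and 10.56, and that of the probe set brightest in control animals has 11.63 and 11.85.

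Over 6609 pairs of probe sets from 4525 genes, 60 pairs of 52 genes moved apart at an adjusted p under 0.05 in limma, and 648 at an unadjusted p under 0.05. In 40 of the 60 pairs only the brighter probe set passed by itself, in 7 only the dimmer, in 7 both moved the same way, in 0 both moved opposite ways and in 6 neither passed. In 21 pairs the partner was at the floor on all 12 arrays. With pairs limited to bright probe sets 15 of 3827 moved apart. The count was 39 without exposed animal 1.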

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

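The tests of RNA quality and of array scaling against the glucocorticoid list, of midbrain tissue in control 4, and of chance and RNA quality for the number sets were chosen only after the result was seen. In 316 groups of 6 animals, a single animal lay far from the others of its group in 18, and chance gives about 1 in 20 groups, or 15.8.

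Control 4 held the most distant value of a list. Its mean over olfactory bulb and neuroblast markers was 0.561 on the log2 scale, with the other controls between -0.143 and -0.077, and its Dcx value was 8.965 with the others between 8.228 and 8.443. A noisy array is argued against, since its spread from the other controls was 1.032 times their median spread. Midbrain tissue, which also makes Th, stays open. The median deviation of 17 other midbrain and hindbrain markers was 0, but this list also holds hindbrain markers, so its median cannot decide. Its member Slc6a3, picked after its values were seen, was 8.562 in control 4 and 7.287 to 8.172 in the other controls. Olfactory bulb tissue in this dissection is a candidate explanation: the median deviation of 5 bulb neuron markers was 1.11 (Cdhr1 2.44, Eomes 1.16, Doc2g 1.11, Th 0.98, Omp 0.95), against 0.141 for 6 neuroblast markers that are expressed more widely. Both marker sets belong to the list whose high mean flagged this animal, so these values are not independent support. Beyond noise and these tissues in the dissection, no explanation was tested.

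The glucocorticoid-induced list was higher in exposed animals. The members that the activity lists also hold (Dusp1 and Cdkn1a) do not carry the shift alone, since without them the camera p was 9.13e-11 (p = 0.0332 with an estimated correlation) and 26 of 28 changes were positive. Scaling of the arrays is argued against by its size, since medians and upper quartiles of the 12 arrays lay within 0.068 of each other while the mean over the list differed by 0.30 (SE 0.07). With RNA quality as a covariate the adjusted camera p was 2.6e-20, which argues against RNA quality as the whole cause only at the preset correlation. This covariate was not run with an estimated correlation. Of 100 permutation splits 3, the real split included, were as strong (real camera p = 3.61e-13). That is under the limit of 5 of 100 set beforehand for excluding chance. Chance is still left open here, since the 2 other splits were stronger, at 3.15e-15 and 2.37e-14. These put 4 and 5 of the 6 animals numbered 4 to 6 together with 5 and 4 exposed animals. A response to the exposure stays open as a hypothesis that was not tested apart from handling, and the call is lost with an estimated correlation (adjusted p = 0.11).

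Animals numbered 4 to 6 differed from those numbered 1 to 3 in both groups, a pattern noticed in the data, with 3 probe sets past the threshold in limma (2645 at an unadjusted p under 0.05), among them Per2. Of the 27 lists 8 passed camera between the sets: glucocorticoid-induced (adjusted p = 5.84e-14), clock (0.00181) and oxidative phosphorylation genes (8.29e-08) were higher in numbers 4 to 6, heat shock (6.65e-05), astrocyte (6.65e-05), microglia (0.00582), interferon (0.00813) and oligodendrocyte genes (0.0299) were lower, and only the glucocorticoid list passed with an estimated correlation (adjusted p = 0.0254). Chance order of the numbers stays open. The sets were noticed on the glucocorticoid list, on which 1 of 100 permutation splits was as strong (real camera p = 2.16e-15, strongest other 5.27e-10). The exact permutation p of that list was 0.005, the smallest this test can give, and 0.0675 after adjustment over the lists. That adjusted value cannot decide, since a list at the smallest p could hardly pass over 27 lists. RNA quality also differed between the sets (-0.073, exact two-sided permutation p = 0.02). With RNA quality as a covariate the camera p of the glucocorticoid list was 2.45e-09. A random split reached 5.27e-10 without the covariate, so this p cannot decide whether RNA quality was the cause. A different hour of the day at collection is a candidate explanation: Bmal1, Npas2 and Clock, which peak opposite to the Per genes, had a mean difference of -0.107 (exact two-sided permutation p = 0.01), although Bmal1 differed by 0.03 in control and -0.19 in exposed animals and Npas2 by -0.24 and -0.01, and the labels give no hour or batch, so handling, a batch or another shared cause stays open too.

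Chance can be excluded for 610 higher probe sets (1 of 100 splits gave as many, highest other 3), for 186 lower ones (1 of 100, highest other 3) and for 60 pairs that moved apart (1 of 100, highest other 3). By the same permutation splits, 1 of 100 as strong in each, it can be excluded for the immediate early list (p = 6.26e-39, strongest other 3.82e-15), the effector list (p = 3.08e-34, strongest other 8.64e-19) and the heat shock list (p = 7.68e-21, strongest other 5.97e-15). It cannot be excluded for the endothelial and mural list (14 of 100 permutation splits as strong, p = 0.00449, strongest other 7.33e-07) or the meningeal and fibroblast list (17 of 100, p = 0.00295, strongest other 1.84e-07).

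Other single animals far from the rest of their group are given as log2 values. In exposed animals, Egr4 was 10.484 in animal 3 (others 10.702 to 10.826), Bdnf 9.678 in animal 5 (others 10.215 to 10.476), Ndufa8 12.835 in animal 5 (others 12.745 to 12.777), the Homer1 probe set with a control mean of 10.85 was 10.676 in animal 5 (others 11.039 to 11.129) and S100a9 7.069 in animal 6 (others 5.867 to 6.207). Among control animals, Zc3h6 was 9.132 (others 9.381 to 9.518), Dnajb5 10.226 (others 10.329 to 10.362) and Ptprz1 11.413 (others 11.522 to 11.587) in animal 5. Grin2b was 9.032 (others 9.316 to 9.470) in control 6 and S100a8 6.404, with the others all at the floor of 5.75. Rps15 was 12.978 in control 1 (others 13.096 to 13.128), Nefl 12.826 in control 2 (others 12.864 to 12.885) and Irf8 6.809 in control 3 (others 6.963 to 7.051). The mean over the effector list was 0.585 in exposed animal 1 (others 0.443 to 0.479) and that over blood markers 0.064 in exposed animal 6 (others -0.134 to -0.075). The 3 prime minus 5 prime difference was 0.586 in exposed animal 3 (others 0.391 to 0.443).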

How the results depend on the processing

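Leaving out control 4 and exposed animals 3 and 5 together, leaving out probe sets at the floor on all arrays, and the term for number sets were chosen only after the result was seen. The 4 response lists that passed kept their direction and passed camera under each alternative, except the glucocorticoid list with an estimated correlation (adjusted p = 0.11). The 610 higher probe sets were 451 to 622 with 1 animal left out. The 186 lower ones were 314 with array weights, 72 with the RNA quality covariate, and 82 without control 4 and exposed animals 3 and 5 together. With 1 animal left out they were 103 (without control 3) to 182, with 112 without control 5, 117 without control 6 and 104 without exposed animal 1. The 60 pairs that moved apart were 15 when both probe sets had to be bright, which leaves fewer pairs, and 26 without control 4 and exposed animals 3 and 5. With 1 animal left out they were 39 (without exposed animal 1) to 65. The 6 glucocorticoid-induced members were 13 without the dimmest 40%, 11 with array weights, 13 with the RNA quality covariate, 10 without probe sets at the floor, 18 with the number sets in the fit and 4 to 9 with 1 animal left out. Beyond the immediate early, effector and glucocorticoid lists 3 lists passed (heat shock, endothelial, meningeal); this count was 1 without _s_at, _x_at and _a_at probe sets, 1 with an estimated correlation, and 1 (without control 3, and without exposed animal 4) to 4 with 1 animal left out. The adjusted p of the endothelial list was 0.0595 without those probe sets, 0.592 with an estimated correlation and 0.00443 to 0.0801 with 1 animal left out (0.0515 without control 2, 0.0539 without control 3, 0.0801 without exposed animal 4 and 0.0766 without exposed animal 6). For the meningeal list it was 0.0595, 0.663 and 0.00152 to 0.0994 (0.0539 without control 3, 0.0994 without exposed animal 4). Except where fewer animals or pairs were tested, the cause was not tested.

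Replicate numbers gave no clear sign that single animals were paired: 2 of 6 correlated best with the same number in the other group, and 2 of 6 correlations were over 0.1 (0.075, -0.071, -0.013, -0.023, 0.167 and 0.128 for numbers 1 to 6). These values do not exclude a pairing. The best partner of numbers 1 to 6 was number 3, 3, 1, 6, 5 and 6, each from the same number set (1 to 3 or 4 to 6). With the replicate block, 359 probe sets were higher, 76 lower and 11 pairs moved apart; the block uses up degrees of freedom.

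For 130 results of named genes, 3482 of 3617 alternatives kept direction and side of the threshold, 93 (17 genes) no longer passed, 42 (18 genes) newly passed and 0 reversed. For lists that had not passed, 627 of 630 were alike, and 3 newly passed (oxidative phosphorylation). Probe sets near the floor have little signal over background, which limits what can be called there.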

Other observations

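The tests in this part, of families of gene symbols and of genes outside the lists, were chosen only after the result was seen, and so were the genes named here. Genes that rose were over-represented among dual-specificity phosphatases, some of which switch off MAP kinases. Of 20 measured Dusp genes, grouped by symbol, 6 passed as higher in exposed animals (Dusp1, Dusp2, Dusp5, Dusp6, Dusp14 and Dusp18), against 372 of 14217 over all genes. Of 447 families of symbols with at least 5 members this was the only one past the threshold (one-sided Fisher's exact p = 8.76e-06, adjusted p = 0.00391). Dusp2 rose 1.75-fold (adjusted p = 0.000356). Dusp18 counts by its brighter probe set, with a log2 change of 0.27 (adjusted p = 0.0255), while its other bright probe set was at -0.01 (adjusted p of the difference 0.00463). Among genes in no list, Irs2, which relays insulin signals, rose 1.92-fold (adjusted p = 1.93e-07), the somatostatin receptor gene Sstr2 1.65-fold (adjusted p = 0.000231), and Dio2, which activates thyroid hormone, 1.67-fold (adjusted p = 0.00735).

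Other pairs of bright probe sets of a gene moved apart. In Nr4a3 the log2 change was 1.32 at the brighter probe set and 0.31 at the other (adjusted p of the difference 0.00651 in limma over all 6609 pairs). In Tent5a it was 0.04 at the brighter and 0.56 at the other (0.0143), in Dclk1 0.06 and 0.47 (0.00396), and in Tnik 0.11 and -0.30 (0.00268).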
